A study of Homo sapiens with 8 samples.

How the data were processed

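RNA was measured by RNA sequencing in 8 libraries of 2 human liver cancer cell lines, MHCC97H and PLC/PRF/5, with 2 control and 2 tigecycline libraries per line after 72 hours of treatment. Per the labels' protocols, cells grew in DMEM with fetal bovine serum, total RNA was extracted with Trizol and libraries were made for Illumina sequencing. Whether libraries kept strand or selected poly(A) RNA is not given in the sources used here, so overlapping and antisense genes are uncertain. The submitters' processing notes name fastp, HISAT and RSEM, with no versions, and the genome build GRCh38.p13. The authors deposited TPM, in which the reads of a gene are divided by its length and scaled to the same total in each library, printed in steps of 0.01. The deposited table also gave a gene length in bases and 4 group means, which were not used here.

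The table held 61329 rows, of which 60671 had Ensembl gene identifiers and 658 were assembled loci without a symbol. Coordinates and gene types came from GENCODE release 29 on GRCh38, which matched 58453 identifiers (96.3%). All libraries were at 0 in 29161 rows, and 76 symbols stood on more than 1 row, which were kept apart by identifier. None of 10 housekeeping genes was at 0 in any library, but 162 tested rows were at 0 in 1 library and at 10 TPM or more in its replicate, so a 0 is given only as listed at 0. TPM keep no read totals, so no counting interval was computed. In rows of 500 to 519 bases, low values were gathered in 2 windows chosen after they were seen, the same in all libraries. Their medians were 0.24 to 0.30 TPM and 0.48 to 0.605 TPM, and 0.25 and 0.51 TPM in PLC/PRF/5 tigecycline replicate 2. The windows bound these medians, so they do not compare depth between libraries. These levels also depend on fragment length.

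Counts had been assumed when the tests were chosen, before the data were examined. Because the values were TPM, the alternative test written for that case was used. Log2(TPM + 1) values of 17141 rows with at least 1 TPM in at least 2 libraries, 13143 of them protein-coding, were fitted with limma 3.58.1 in R 4.3.3, with the R package data.table (version 1.17.8) for reading, a mean per group and a variance trend on mean level. The fit had 4 residual and 2.86 prior degrees of freedom. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of low genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 were called. Tigecycline was compared with control in each line, the change in PLC/PRF/5 was compared with that in MHCC97H, the control lines were compared with each other, and a model with the line as a covariate (5 residual degrees of freedom) gave the change across both lines.

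Gene lists, 35 in all, were fixed at the same time for mitochondrial, stress, metabolic, proliferation, hepatocyte, interferon, ribosomal and other themes, and for markers of leukocytes, fibroblasts, endothelial cells and cholangiocytes. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. Camera compares a list with all other genes. Fry tests whether the genes of a list move, on balance, in a direction. Each contrast's list p-values were adjusted over the 35 lists, and gene counts are given over all tested genes and adjusted over the list alone.

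Named genes followed a rule fixed with the tests. It took 20 chosen genes of the stress response, mitochondria, cell cycle and liver in both lines, called or not, and the 6 highest and 6 lowest log2 fold changes per line among called genes with a symbol, at least 10 TPM on average in the higher group and both treated libraries on the same side of both controls. It also took the 5 highest and 5 lowest in the difference between the lines, by the same rule without the condition on sides, the 4 highest and 4 lowest between the control lines, and up to 4 members with the smallest p of each list described, with any called member of a list of which 5 or fewer were called. Histone, antisense and near-identical paralog genes kept their place and are marked as uncertain. Results of 4 genes that the rule took are not reported here.

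The fit was tested on simulated data with 200 changed genes among 17141. It recovered 52% of changes of 1 and 89% of changes of 2 on the log2 scale in each line. The direction was right in 100%, with 5 false calls in MHCC97H and 7 in PLC/PRF/5. Noise was drawn per gene from the fit's own variance model, independent and equal in all groups. Few false calls were therefore built in, and these values give no error rate for the real libraries. Alternatives were median-of-ratios and upper-quartile scaling, leaving out mitochondrially encoded genes, no filter, a filter at 5 TPM, protein-coding genes alone, a pseudocount of 0.1, each line fitted alone, the replicate number as a block, stricter thresholds and each library left out. Leaving out rows shorter than 300 bases was chosen after seeing the data.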

Results

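The transcriptomes of 2 human liver cancer cell lines were compared after 72 hours with tigecycline or with DMSO, the solvent used for the control cells. Tigecycline is a glycylcycline antibiotic that binds the bacterial ribosome and also inhibits protein synthesis by the related ribosomes of mitochondria. MHCC97H is a hepatocellular carcinoma line selected for its high metastatic potential, and PLC/PRF/5 is a hepatoma line that carries integrated hepatitis B virus DNA. Each line contributed 2 control and 2 tigecycline libraries, which gave 4 groups and 8 libraries, and the series set out to profile the mRNA of tigecycline-treated cells. The concentration of tigecycline is not given in the sources used here. Expression was given as TPM, transcript shares corrected for gene length and scaled to the same total in each library, so read totals are not given. Low values of rows of 500 to 519 bases had medians of 0.24 to 0.30 TPM in the 8 libraries. They were taken inside a fixed window chosen after the values were seen, so they cannot show whether depth was similar. In rows of about 1 kb, the commonest value below 1 TPM was 0.16 in PLC/PRF/5 tigecycline replicate 2 and 0.08 to 0.1 in the other libraries. That library also had low values in such rows around 0.08 TPM (18 values), beside those around 0.17 TPM (25 values). Its commonest value of 0.16 therefore does not show a lower depth. Between 14101 and 14900 genes reached 1 TPM in a library, and mRNAs encoded by mitochondrial DNA made up 11.8% to 16.1% of the TPM. The 2 libraries of a group correlated at r = 0.981 to 0.985 across 17141 tested genes, which are not independent replicates. Small noncoding RNAs differed between the libraries. Their sum was 1845 and 1733 TPM in the MHCC97H controls against 1039 and 895 TPM with tigecycline, and 1543 and 1482 TPM in the PLC/PRF/5 controls against 2606 and 7787 TPM with tigecycline. No label says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

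In MHCC97H, gene lists of the integrated stress response, amino acid synthesis and aminoacyl-tRNA synthesis passed camera upward with tigecycline, and those of DNA replication, mitosis and cholesterol synthesis passed downward. None of these lists passed with an estimated correlation (adjusted p = 0.0682 to 0.301). ASNS, which makes asparagine (ENSG00000070669, GRCh38 chromosome 7, 97852118 to 97872542), rose to 261.7 ± 9.66 TPM (SD, n = 2) by a log2 fold change of 2.51 (SE 0.07, limma adjusted p = 1.71e-05). CHAC1, an enzyme that degrades glutathione (ENSG00000128965, chromosome 15, 40952962 to 40956519), went from 2.99 ± 0.919 TPM (SD, n = 2) in controls to 31.7 ± 4.84 TPM. Of 24 measured ATF4 and integrated stress response genes, 21 rose and none fell, and 22 rose when adjusted over the list alone. The median log2 fold change of this list was 1.30 (camera adjusted p = 2.81e-25, and adjusted p = 0.0682 with an estimated correlation). SESN2, a stress-induced regulator of mTORC1 signalling, rose from 9.10 to 51.1 TPM (log2 fold change 2.37, SE 0.10, limma adjusted p = 1.00e-04). GDF15, a secreted stress cytokine, rose from 71.3 to 390.2 TPM (log2 fold change 2.42, SE 0.11, limma adjusted p = 1.46e-04). The transcription factors ATF4 and DDIT3 rose by 1.03 (SE 0.07) and 1.59 (SE 0.16) on the log2 scale, and TRIB3, a pseudokinase induced by both, by 1.60 (SE 0.08). FGF21, another ATF4 target, averaged 0.600 TPM with tigecycline, below the level required for testing, and was listed at 0 in both controls. It was below that level in PLC/PRF/5 as well.

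Of 18 enzymes of serine, glycine and other amino acid synthesis, 12 rose and 2 fell in MHCC97H, and 12 rose and 3 fell when adjusted over the list alone. For these 18 enzymes, the median log2 fold change was 1.01 (camera adjusted p = 7.47e-09, and adjusted p = 0.105 with an estimated correlation). PHGDH, which begins serine synthesis, rose from 8.98 ± 1.81 to 89.5 ± 1.88 TPM (log2 fold change 3.19, SE 0.12, limma adjusted p = 4.77e-05). PSAT1, the next enzyme of that pathway, rose by 1.93 (SE 0.06), and CBS, which makes cystathionine, by 1.58 (SE 0.06). Of 20 cytosolic tRNA synthetases, 12 rose and none fell, the same counts as when adjusted over the list alone. For these cytosolic tRNA synthetases, the median log2 fold change was 0.63 (camera adjusted p = 1.11e-09, and adjusted p = 0.0841 with an estimated correlation). GARS1 and SARS1, the glycyl- and seryl-tRNA synthetases, rose by 1.46 (SE 0.05) and 1.40 (SE 0.06).

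**Figure D1:**
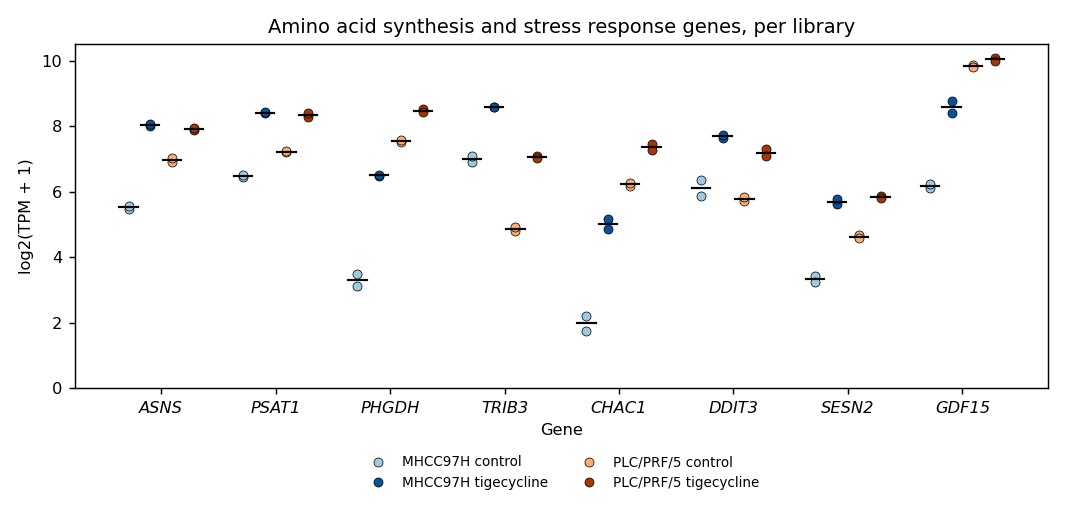
Each point is the log2(TPM + 1) of 1 library for 8 stress response and amino acid synthesis genes in the 4 groups, and each bar is the mean of the 2 libraries of a group. All 8 genes were higher with tigecycline in MHCC97H, and 7 of them passed the test in PLC/PRF/5, where GDF15 had a log2 fold change of 0.21 (limma adjusted p = 0.213).

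Proliferation genes went down in MHCC97H. Of 33 DNA replication genes, 29 fell and none rose, and 32 fell when adjusted over the list alone. For these DNA replication genes, the median log2 fold change was -0.88 (camera adjusted p = 2.81e-19, and adjusted p = 0.206 with an estimated correlation). TYMS, the thymidylate synthase (ENSG00000176890, chromosome 18, 657604 to 673578), fell from 113.6 ± 6.05 to 39.3 ± 2.80 TPM (log2 fold change -1.51, SE 0.07, limma adjusted p = 1.74e-04). RRM2, a subunit of ribonucleotide reductase, and MCM2, a subunit of the replicative helicase, had log2 fold changes of -1.20 (SE 0.07) and -1.04 (SE 0.08). Of 34 mitosis genes, 27 fell and none rose, and 31 fell when adjusted over the list alone (median -0.60, camera adjusted p = 2.25e-15, and adjusted p = 0.271 with an estimated correlation). CDK1 and BIRC5, the mitotic kinase and a subunit of the chromosomal passenger complex, had log2 fold changes of -0.92 (SE 0.09) and -0.83 (SE 0.06), and CCNB1 and MKI67 of -0.58 (SE 0.07) and -0.60 (SE 0.10). The call of MKI67 was lost without tigecycline replicate 2. CDKN1A, the cell cycle inhibitor induced by p53, was at 48.5 ± 13.4 TPM in controls and 56.5 ± 0.530 TPM with tigecycline (limma adjusted p = 0.489), and MYC at 148.7 ± 27.4 and 194.2 ± 20.2 TPM (limma adjusted p = 0.122).

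Lists of lipid synthesis, respiratory chain and chaperone genes also passed camera downward in MHCC97H, and none passed with an estimated correlation. Of 24 cholesterol synthesis genes, 11 fell and none rose, and 19 fell when adjusted over the list alone. For these cholesterol synthesis genes, the median log2 fold change was -0.67 (camera adjusted p = 2.62e-08, and adjusted p = 0.301 with an estimated correlation). Of 76 nuclear-encoded respiratory chain subunits, 34 fell and none rose, with 1 higher and 41 lower when adjusted over the list alone. For these nuclear-encoded respiratory chain subunits, the median log2 fold change was -0.27 (camera adjusted p = 1.15e-08, and adjusted p = 0.335 with an estimated correlation). ATP5MF of the ATP synthase had a log2 fold change of -0.54 (SE 0.06) and NDUFAB1 of complex I of -0.52 (SE 0.06). Among 19 genes of endoplasmic reticulum stress, 11 fell and 3 rose, and 11 fell and 4 rose when adjusted over the list alone (median -0.43, camera adjusted p = 0.00484, and adjusted p = 0.164 with an estimated correlation). The chaperones CALR and PDIA4 went from 675.5 to 333.0 and from 227.3 to 113.6 TPM, while HSPA5, the main chaperone of this compartment, was at 246.2 ± 18.9 and 268.4 ± 24.8 TPM (limma adjusted p = 0.359). Of 15 cytosolic heat shock genes, 6 fell and none rose, and 9 fell when adjusted over the list alone, HSPB1 among them with -0.50. For these cytosolic heat shock genes, the median log2 fold change was -0.28 (camera adjusted p = 7.64e-04, and adjusted p = 0.271 with an estimated correlation). Of 15 fatty acid synthesis genes, 5 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone, with -1.38 for the desaturase FADS2. For these fatty acid synthesis genes, the median log2 fold change was -0.31 (camera adjusted p = 0.0225, and adjusted p = 0.271 with an estimated correlation).

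Other lists in MHCC97H shifted in both directions. Of 29 lysosome and autophagy genes, 8 rose and 3 fell, and 11 rose and 3 fell when adjusted over the list alone, with MAP1LC3B of the autophagosome membrane up by 1.44 (SE 0.06) and the lysosomal cholesterol transporter NPC1 by 0.71 (SE 0.07). For these lysosome and autophagy genes, the median log2 fold change was 0.10 (camera adjusted p = 0.00218, and adjusted p = 0.164 with an estimated correlation). Of 20 senescence-associated secretory genes, 4 rose and 2 fell, and 8 rose and 2 fell when adjusted over the list alone. For these senescence-associated secretory genes, the median log2 fold change was 0.30 (camera adjusted p = 0.00218, and adjusted p = 0.164 with an estimated correlation). The cell cycle inhibitor CDKN2B rose by 1.52 (SE 0.14), while the chemokines CXCL1 and CXCL8 had log2 fold changes of -1.23 (SE 0.13) and -2.03 (SE 0.32). Of 20 glycolysis genes, 10 fell and 1 rose, and 11 fell and 2 rose when adjusted over the list alone, with -0.66 for PGAM1, which has many near-identical pseudogenes, and -0.59 for PFKFB3. For these glycolysis genes, the median log2 fold change was -0.32 (camera adjusted p = 0.00218, and adjusted p = 0.335 with an estimated correlation). The glycolysis call was lost without control replicate 2 (camera adjusted p = 0.0522). Of 78 cytosolic ribosomal protein genes, whose many pseudogenes make single members uncertain, 21 fell and 2 rose, and 26 fell and 2 rose when adjusted over the list alone, RPS26 and RPS21 among them with -0.74 and -0.69. For these cytosolic ribosomal protein genes, the median log2 fold change was -0.13 (camera adjusted p = 9.91e-04, and adjusted p = 0.608 with an estimated correlation). That call was lost under median-of-ratios scaling (camera adjusted p = 0.273) and without control replicate 2 (camera adjusted p = 0.212). Of 30 hepatocyte protein genes, 8 fell and none rose, and 9 fell and 1 rose when adjusted over the list alone, FGA and FGB of fibrinogen among them with -1.16 and -2.40. For these hepatocyte protein genes, the median log2 fold change was -0.16 (camera adjusted p = 0.0354, and adjusted p = 0.329 with an estimated correlation). This call was lost when MHCC97H was fitted alone (camera adjusted p = 0.133) and without control replicate 1 (0.1196), tigecycline replicate 2 (0.0537) or any 1 of the 4 PLC/PRF/5 libraries (0.0515 to 0.0543). ALB, the albumin gene, went from 30.5 ± 19.7 to 4.80 ± 3.15 TPM (limma adjusted p = 0.0213), a call lost without control replicate 1 or tigecycline replicate 2.

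The largest rises in MHCC97H, by the rule fixed for naming genes, were in IGFBP1, NIBAN1, PGAM1P5, PHGDH, ITPKA and AREG. IGFBP1, a secreted insulin-like growth factor binding protein (ENSG00000146678, chromosome 7, 45888357 to 45893668), went from 3.66 ± 1.03 to 120.2 ± 14.1 TPM (log2 fold change 4.71, SE 0.16, limma adjusted p = 4.04e-05). NIBAN1, a stress-induced gene, went from 0.175 to 17.8 TPM, ITPKA, an inositol trisphosphate kinase, from 32.0 to 299.4 TPM, and AREG, a ligand of the epidermal growth factor receptor, from 16.5 to 152.3 TPM. PGAM1P5 is a pseudogene with 13.3 ± 13.7 TPM after tigecycline and is uncertain, and its call was lost without either control library. The largest falls were in ITM2A (182.7 ± 88.0 to 13.2 ± 7.89 TPM), the tight junction gene CLDN2 (log2 fold change -3.48), the alcohol dehydrogenase ADH1C (-3.24), the vitamin D hydroxylase CYP24A1 (-2.88), ASB4 (-2.73) and the matrix glycoprotein THBS1 (-2.46, lost without any 1 of the 4 MHCC97H libraries). LONP1, a mitochondrial protease, rose from 105.8 ± 1.10 to 191.7 ± 1.82 TPM, and the mitochondrial chaperonin HSPD1 was at 895.7 ± 62.0 and 787.4 ± 30.3 TPM (limma adjusted p = 0.0844). TNFRSF10B, a death receptor, rose by 0.52 (SE 0.07) on the log2 scale.

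Across 17141 genes, limma called 2744 in MHCC97H at an adjusted p below 0.05, of which 1076 were higher and 1668 lower with tigecycline. The split between directions depended on scaling, with 1525 higher and 1171 lower under median-of-ratios scaling. Of the 2744 genes, 295 were more than doubled and 296 fell to less than 50% of control on the log2(TPM + 1) scale. When MHCC97H was fitted without the PLC/PRF/5 libraries the count fell to 108, 73 higher and 35 lower, so most list members counted as lower in MHCC97H were not called in that fit, while camera passed 15 lists. The count fell to 1559, 1239 and 1465 without control replicate 1, tigecycline replicate 1 and tigecycline replicate 2. Camera passed 16 of 35 gene lists, 6 upward and 10 downward, and 0 with an estimated correlation, while fry passed 23 and 18 had an unadjusted camera p below 0.05. Markers of leukocytes, fibroblasts, endothelial cells and cholangiocytes did not pass (camera adjusted p = 0.593, 0.463, 0.312 and 0.743). Only 4 of 17, 3 of 12, 3 of 10 and 7 of 9 of these markers were measured, so their tests say little. Fry passed the endothelial list upward (fry adjusted p = 0.0192), with 2 genes higher and 1 lower.

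In PLC/PRF/5, lists of integrated stress response, tRNA synthetase and ribosomal protein genes passed camera upward with tigecycline, and lists of interferon-stimulated, mitosis and cholesterol synthesis genes passed downward. None of them passed with an estimated correlation (adjusted p = 0.0853 to 0.446). Of 21 measured interferon-stimulated genes, 17 fell and none rose, and 18 fell when adjusted over the list alone. For these interferon-stimulated genes, the median log2 fold change was -1.32 (camera adjusted p = 4.30e-08, and adjusted p = 0.128 with an estimated correlation). ISG15, a ubiquitin-like protein induced by interferon (ENSG00000187608, chromosome 1, 1001138 to 1014540), went from 1530 ± 117 to 165.3 ± 7.32 TPM (log2 fold change -3.20, SE 0.07, limma adjusted p = 1.83e-05). IFIT1, which binds viral RNA (ENSG00000185745, chromosome 10, 89392546 to 89406486), went from 39.4 ± 1.68 to 0.665 ± 0.0495 TPM (log2 fold change -4.60, SE 0.19, limma adjusted p = 1.12e-04). OASL, of the same list, had a log2 fold change of -2.17 (SE 0.19). In MHCC97H, 1 of the 21 genes rose, 2 fell and the list did not pass (median -0.17, camera adjusted p = 0.371).

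**Figure D2:**
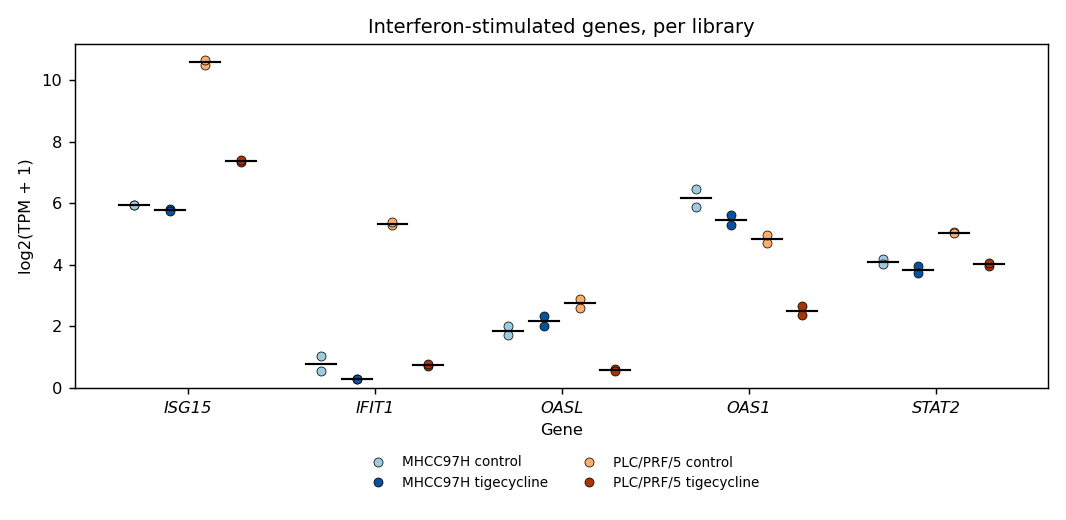
Each point is the log2(TPM + 1) of 1 library for 5 interferon-stimulated genes in the 4 groups, and each bar is the mean of the 2 libraries of a group. In PLC/PRF/5 all 5 fell with tigecycline, ISG15 from 1530 to 165.3 TPM, and in MHCC97H none of the 5 passed the test. OAS1 and STAT2 were chosen after their values were seen, as members above 10 TPM in the MHCC97H controls.

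Stress response genes rose in PLC/PRF/5 in nearly the numbers seen in MHCC97H. Of 24 ATF4 and integrated stress response genes, 21 rose and 1 fell, the same counts as when adjusted over the list alone. For these ATF4 and integrated stress response genes, the median log2 fold change was 1.10 (camera adjusted p = 1.95e-15, and adjusted p = 0.0853 with an estimated correlation). TRIB3 (ENSG00000101255, chromosome 20, 362835 to 397559) rose from 28.3 ± 1.63 to 132.2 ± 2.86 TPM (log2 fold change 2.19, SE 0.08, limma adjusted p = 9.48e-05). The amino acid transporter SLC7A5 and the transcription factor JDP2 rose by 1.66 (SE 0.11) and 1.75 (SE 0.13), and STC2, a secreted glycoprotein, by 1.33 (SE 0.10). CHAC1 and DDIT3 rose by 1.14 (SE 0.17) and 1.41 (SE 0.16). ATF4 rose by 0.33 (SE 0.07), a call lost without control replicate 2 or either tigecycline library. Of 18 enzymes of amino acid synthesis, 12 rose and 2 fell, and 13 rose and 3 fell when adjusted over the list alone, with 0.94 for ASNS, 1.11 for PSAT1 and 0.94 for the alanine transaminase GPT2. For these enzymes of amino acid synthesis, the median log2 fold change was 0.74 (camera adjusted p = 6.21e-07, and adjusted p = 0.128 with an estimated correlation). Of 20 tRNA synthetases, 14 rose and 1 fell, and 15 rose and 1 fell when adjusted over the list alone, with WARS1 up by 1.38 and GARS1 by 0.92. For these tRNA synthetases, the median log2 fold change was 0.49 (camera adjusted p = 7.96e-11, and adjusted p = 0.0853 with an estimated correlation).

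Of 34 mitosis genes in PLC/PRF/5, 29 fell and none rose, and 30 fell when adjusted over the list alone, NUSAP1 and PLK1 with log2 fold changes of -1.43 (SE 0.12) and -0.75 (SE 0.08). For these mitosis genes, the median log2 fold change was -0.67 (camera adjusted p = 4.64e-11, and adjusted p = 0.375 with an estimated correlation). CCNB1 had a log2 fold change of -0.52 (SE 0.07), and MKI67 of -0.33 (SE 0.10, limma adjusted p = 0.0482), the latter lost without any 1 of the 4 PLC/PRF/5 libraries or either MHCC97H tigecycline library. Of 33 DNA replication genes, 14 fell and none rose, and 20 fell and 1 rose when adjusted over the list alone, with -0.71 for MCM3 and -0.61 for PCNA, the last lost without control replicate 1 or tigecycline replicate 1. For these DNA replication genes, the median log2 fold change was -0.33 (camera adjusted p = 0.00180, and adjusted p = 0.555 with an estimated correlation). Of 24 cholesterol synthesis genes, 20 fell and none rose, and 21 fell when adjusted over the list alone. For these cholesterol synthesis genes, the median log2 fold change was -0.84 (camera adjusted p = 9.13e-08, and adjusted p = 0.375 with an estimated correlation). IDI1 and DHCR7 of this pathway had log2 fold changes of -1.65 and -0.94. CDKN1A rose by 0.67 on the log2 scale (SE 0.20, limma adjusted p = 0.0499), a call lost without any 1 of the 4 PLC/PRF/5 libraries or either MHCC97H tigecycline library, and MYC was at 103.9 ± 2.98 and 88.9 ± 11.6 TPM (limma adjusted p = 0.296).

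Of 78 cytosolic ribosomal protein genes in PLC/PRF/5, 31 rose and 4 fell, and 36 rose and 4 fell when adjusted over the list alone, with 0.73 for RPL12 and 0.50 each for RPS6 and RPS19. For these cytosolic ribosomal protein genes, the median log2 fold change was 0.16 (camera adjusted p = 1.87e-12, and adjusted p = 0.446 with an estimated correlation). Of 28 ribosome biogenesis genes and MYC targets, 7 rose and 2 fell, and 11 rose and 2 fell when adjusted over the list alone, with 1.06 for RRP12 and -0.46 for the nucleolar methyltransferase FBL, the last lost without control replicate 1. For these ribosome biogenesis genes and MYC targets, the median log2 fold change was 0.15 (camera adjusted p = 6.50e-04, and adjusted p = 0.538 with an estimated correlation). Of 23 fatty acid oxidation genes, 10 fell and 1 rose, and 12 fell and 1 rose when adjusted over the list alone, with -2.33 for PDK4, the kinase that shuts off pyruvate dehydrogenase, and -1.05 for the dehydrogenase HADH. For these fatty acid oxidation genes, the median log2 fold change was -0.39 (camera adjusted p = 0.00618, and adjusted p = 0.299 with an estimated correlation). Of 20 glycolysis genes, 12 fell and 2 rose, and 13 fell and 2 rose when adjusted over the list alone, with -1.30 for PFKFB3 and -0.78 for LDHA. For these glycolysis genes, the median log2 fold change was -0.47 (camera adjusted p = 0.00670, and adjusted p = 0.446 with an estimated correlation). Of 24 NRF2 targets, 7 rose and 4 fell, and 8 rose and 4 fell when adjusted over the list alone, with 1.36 for AKR1C1, 1.59 for AKR1C2 and 1.18 for the ferritin heavy chain gene FTH1, all of which have near-identical copies and are uncertain. For these NRF2 targets, the median log2 fold change was 0.16 (camera adjusted p = 0.0114, and adjusted p = 0.284 with an estimated correlation). Of 78 mitochondrial ribosome genes, 11 rose and 7 fell, and 10 rose and 7 fell when adjusted over the list alone, with 0.78 for MRPS10 and 0.72 for MRPL21. The median of this list was 0.03 (camera adjusted p = 0.0174, and adjusted p = 0.347 with an estimated correlation), a list call lost without control replicate 1. All tested genes in PLC/PRF/5 had a median log2 fold change of -0.10, and 26.6% of them were called. Camera compares a list with these genes, so a list can pass upward with a median near 0. Fry did not pass the mitochondrial ribosome list or the ribosome biogenesis and MYC target list (fry adjusted p = 0.112 for each).

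The calls of 3 more lists in PLC/PRF/5 were fragile. Of 20 senescence-associated secretory genes, 3 rose and 1 fell, the same counts as when adjusted over the list alone, the inflammatory chemokine CXCL8 going from 114.9 ± 6.02 to 526.5 ± 10.9 TPM and CDKN2B from 0.665 to 2.61 TPM. For these senescence-associated secretory genes, the median log2 fold change was 0.05 (camera adjusted p = 0.0389, and adjusted p = 0.299 with an estimated correlation). Of 15 heat shock genes, 6 fell and none rose, and 8 fell when adjusted over the list alone, with -0.68 for HSPA1B, which has a near-identical copy, and -0.25 for STIP1. For these heat shock genes, the median log2 fold change was -0.19 (camera adjusted p = 0.0389, and adjusted p = 0.446 with an estimated correlation). Of 24 death receptor and apoptosis regulators, 7 rose and 3 fell, and 7 rose and 4 fell when adjusted over the list alone. For these death receptor and apoptosis regulators, the median log2 fold change was 0.15 (camera adjusted p = 0.0459, and adjusted p = 0.299 with an estimated correlation). Their members that moved included the receptor TNFRSF10B with 0.60 and the caspase inhibitor BIRC3 with 0.70, while BMF, a BCL2 family member that promotes apoptosis, had -1.28. The secretory call was lost without control replicate 2 (camera adjusted p = 0.0711) or tigecycline replicate 2 (0.108) and under both other scalings (0.104 and 0.0791), with no filter (0.0833) and with a pseudocount of 0.1 (0.0581). The heat shock call was lost without control replicate 1 (0.112) or tigecycline replicate 2 (0.0746) and under both other scalings (0.367 and 0.245), with a filter at 5 TPM (0.0600) and with protein-coding genes alone (0.0546). The death receptor call was lost without any 1 of the 4 PLC/PRF/5 libraries (0.0518 to 0.0724), with PLC/PRF/5 fitted alone (0.0536), with a filter at 5 TPM (0.0723), with protein-coding genes alone (0.0546) and with a pseudocount of 0.1 (0.0522). The gene call of HSPA1B was lost without control replicate 1 or tigecycline replicate 1, and that of STIP1 without control replicate 1 or tigecycline replicate 2. LONP1 rose from 131.8 ± 3.87 to 221.1 ± 16.2 TPM, while HSPD1 was at 803.7 ± 3.39 and 849.6 ± 7.87 TPM (limma adjusted p = 0.371) and HSPA5 at 408.0 ± 4.52 and 405.3 ± 3.51 TPM (limma adjusted p = 0.975). ALB had a log2 fold change of -1.69 (SE 0.50) and 15.7 ± 1.53 TPM with tigecycline (limma adjusted p = 0.0464), a call lost without any 1 of the 4 PLC/PRF/5 libraries.

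By the rule for naming genes, 5 of the 6 largest rises in PLC/PRF/5 were noncoding RNAs. The sum of small noncoding RNAs, a class that takes in rRNAs and snoRNAs such as these, was also higher in the tigecycline libraries. It was 2606 and 7787 TPM against 1543 and 1482 TPM in controls. In PLC/PRF/5, 5 nuclear RNAs without poly(A) tails had a median log2 fold change of 1.19, and in MHCC97H of -1.21. Whether the largest rises reflect the recovery of such RNAs was not tested. The ribosomal RNA genes RNA5-8SN5, RNA5-8SN4, RNA5-8SN1 and RNA5-8SN2 carried identical values, 3.05 ± 4.11 TPM in controls and 178.1 ± 77.2 TPM with tigecycline, and are uncertain as copies of the same sequence. SNORA63 was listed at 0 in both controls and averaged 58.8 TPM with tigecycline, and SNORA22 averaged 72.8 TPM in controls and was listed at 0 in both tigecycline libraries. The sixth rise was S100P, a calcium-binding protein (ENSG00000163993, chromosome 4, 6693069 to 6697170), from 116.2 ± 21.7 to 1295 ± 129 TPM (log2 fold change 3.48, SE 0.14, limma adjusted p = 1.12e-04). Besides SNORA22, IFIT1 and ISG15, the largest falls were in the fatty acid binding protein gene FABP1 (36.5 ± 1.41 to 2.54 ± 0.891 TPM), the imprinted noncoding RNA H19 (log2 fold change -3.16, SE 0.36) and the noncoding RNA VPS13B-DT (-3.06, SE 0.15). Among protein-coding genes alone, a restriction chosen after the values were seen, the next largest rises were in TRIM29 (3.29), BOLA2 (3.25, uncertain because of near-identical copies and lost without control replicate 2 or tigecycline replicate 1), NIBAN1 (3.21), BEX2 (2.83) and the activin subunit INHBE (2.80). The next largest falls were in the glycoprotein hormone subunit CGA (-3.02), SEMA3D (-2.89) and the creatine kinase CKB (-2.88).

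Limma called 4560 genes in PLC/PRF/5, of which 1499 were higher and 3061 lower. The split was 2277 higher and 1877 lower under median-of-ratios scaling and 2052 higher and 2107 lower under upper-quartile scaling. Of the 4560 genes, 342 were more than doubled and 639 fell to less than 50% of control on the log2(TPM + 1) scale. The count was 2142, 1929, 1932 and 2948 without control replicate 1, control replicate 2, tigecycline replicate 1 and tigecycline replicate 2. Camera passed 16 lists, 9 upward and 7 downward, and 0 with an estimated correlation, while fry passed 22 and 16 had an unadjusted camera p below 0.05. The few measured leukocyte, fibroblast, endothelial and cholangiocyte markers did not pass (camera adjusted p = 0.594, 0.995, 0.888 and 0.955). Fry passed the leukocyte list downward (fry adjusted p = 0.0356), with 2 of 4 genes lower.

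**Figure D3:**
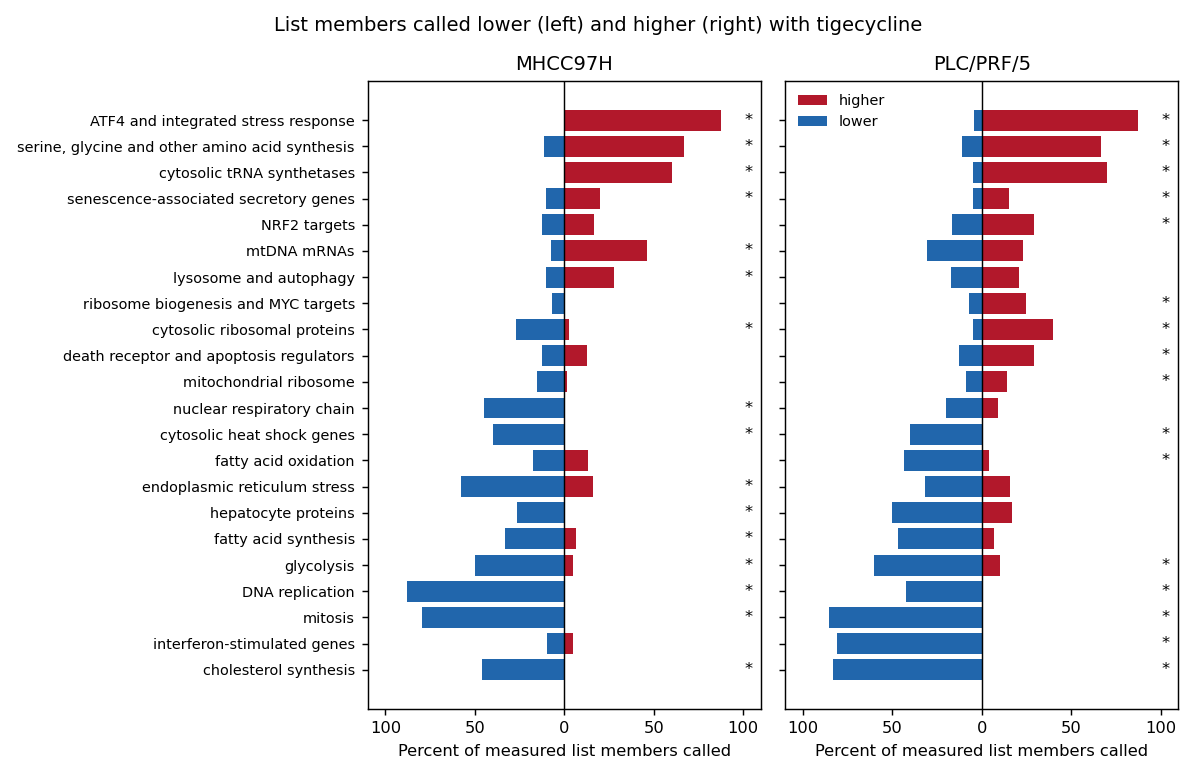
Bars show the percent of measured members of each gene list called lower (to the left, blue) or higher (to the right, red) with tigecycline in each line, for lists that passed camera in at least 1 line, and an asterisk marks an adjusted p below 0.05. The integrated stress response list had 21 of 24 members higher in each line, and 17 of 21 interferon-stimulated genes were lower in PLC/PRF/5 against 2 of 21 in MHCC97H.

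RNAs encoded by mitochondrial DNA did not move together. MT-ND1, a subunit of complex I (mitochondrial chromosome, 3307 to 4262), rose from 3100 ± 98.6 to 4515 ± 127 TPM in MHCC97H and from 2960 ± 169 to 5728 ± 436 TPM in PLC/PRF/5. MT-ND2 rose by 0.67 (SE 0.10) and 0.84 (SE 0.10) on the log2 scale, and MT-CYB by 1.12 (SE 0.07) and 0.42 (SE 0.07). The large rRNA MT-RNR2 had log2 fold changes of -0.96 (SE 0.22, limma adjusted p = 0.0310) in MHCC97H and -0.78 (SE 0.22, limma adjusted p = 0.0421) in PLC/PRF/5, and MT-ND6, the only mRNA of the light strand, of -0.55 (SE 0.13) in each line. The small rRNA MT-RNR1 fell in MHCC97H (-0.96, SE 0.25, limma adjusted p = 0.0440), and its value in PLC/PRF/5 was -0.65 (SE 0.25, limma adjusted p = 0.0992). MT-CO1 had 0.23 in MHCC97H and -0.24 in PLC/PRF/5 (limma adjusted p = 0.186 and 0.125). MT-CO3 and MT-ATP6 rose in MHCC97H by 0.33 and 0.42, and MT-ND4 and MT-ND5 had -0.28 and -0.49 in PLC/PRF/5. The calls of MT-RNR1, MT-RNR2, MT-ND6, MT-CO3 and MT-ND4 were each lost without any of several single libraries, from 3 for MT-ND6 in PLC/PRF/5 to 7 for MT-ND4, and those of MT-RNR1 and MT-ND6 in MHCC97H and of MT-RNR2, MT-ND4 and MT-ND6 in PLC/PRF/5 also under median-of-ratios scaling. In PLC/PRF/5 the call of MT-CYB was lost without control replicate 2 or tigecycline replicate 1, and that of MT-ND5 without control replicate 1 or tigecycline replicate 1. Of the 13 mRNAs, 6 rose and 1 fell in MHCC97H, the same counts as when adjusted over the list alone (median 0.23, camera adjusted p = 4.34e-05, and adjusted p = 0.301 with an estimated correlation). In PLC/PRF/5, 3 rose and 4 fell, and 4 rose and 4 fell when adjusted over the list alone (median -0.03, mean 0.08, camera direction upward, adjusted p = 0.474). The overlapping pairs of MT-ATP8 with MT-ATP6 and MT-ND4L with MT-ND4 share sequence and are uncertain. The rRNAs moved with other RNAs that lack a poly(A) tail in MHCC97H, where 5 nuclear ones had a median log2 fold change of -1.21, and against them in PLC/PRF/5, where the median was 1.19.

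**Figure D4:**
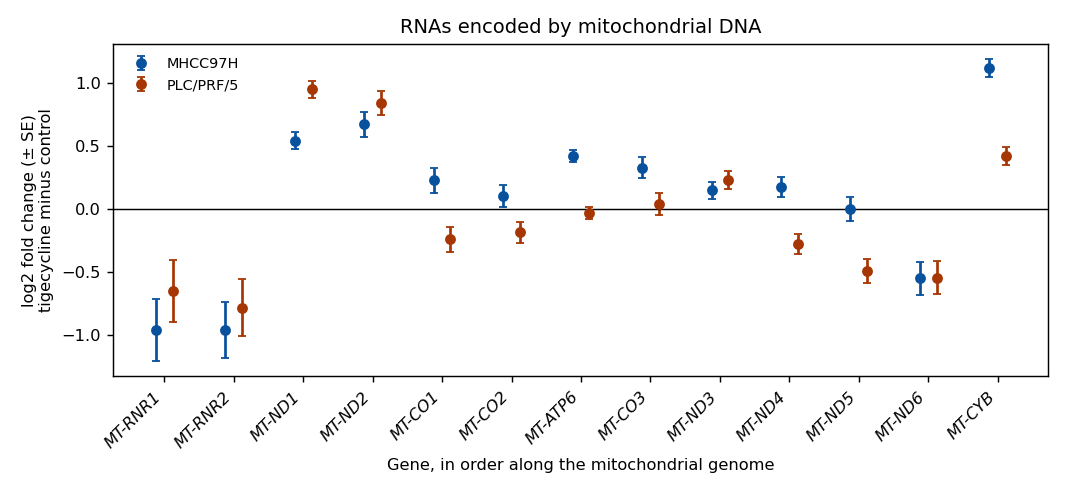
Points give the log2 fold change, tigecycline minus control, with its standard error for 11 mRNAs and 2 rRNAs in their order along the mitochondrial genome, in each line. MT-ND1, MT-ND2 and MT-CYB lie above 0 in both lines, and MT-RNR2 and MT-ND6 lie below 0 in both.

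The test of the difference between the lines, the change in PLC/PRF/5 minus the change in MHCC97H, asked where the 2 lines responded unequally. Interferon-stimulated genes changed more negatively in PLC/PRF/5, with 12 of 21 lower in the difference and none higher, and 17 lower when adjusted over the list alone (median log2 difference -0.95, camera adjusted p = 1.60e-08, and adjusted p = 0.286 with an estimated correlation). Among genes, the lowest differences were in SNORA22, IGFBP1 (-4.31, SE 0.22), IFIT1 (-4.10, SE 0.27), the hypoxia-inducible gene NDRG1 (-3.58, SE 0.50) and ITPKA (-3.43, SE 0.11). IGFBP1 was already at 1183 ± 109 TPM in the PLC/PRF/5 controls and 1559 ± 93.2 TPM with tigecycline. The highest differences were in the same RNA5-8SN copies and SNORA63, of a class whose sum fell in MHCC97H and rose in PLC/PRF/5. Among protein-coding genes, chosen after the values were seen, they were BOLA2 (5.22), CXCL8 (4.21, SE 0.45), the ubiquitin-like modifier UBD (3.66, SE 0.33), ITM2A (3.60) and THBS1 (3.48). CXCL8 had -2.03 in MHCC97H and 2.19 in PLC/PRF/5, and UBD -2.19 and 1.47. The difference of BOLA2 was lost without any 1 of 3 libraries, and those of ITM2A and THBS1 without any 1 of 4.

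Cytosolic ribosomal proteins rose in PLC/PRF/5 relative to MHCC97H, with 34 of 78 higher and none lower, and 45 higher and 1 lower when adjusted over the list alone (median log2 difference 0.32, camera adjusted p = 1.34e-16, and adjusted p = 0.438 with an estimated correlation). Other protein-coding genes matched to them on length and level had a median difference of 0.234. DNA replication genes fell less in PLC/PRF/5, with 15 of 33 higher in the difference and none lower, and 20 higher when adjusted over the list alone, TYMS at 1.18 and RRM2 at 0.86 (median 0.54, camera adjusted p = 5.16e-11, and adjusted p = 0.438 with an estimated correlation). The respiratory chain (9 higher and 2 lower of 76), ribosome biogenesis and MYC target (7 and 0 of 28), mitochondrial ribosome (11 and 0 of 78) and endoplasmic reticulum stress (6 and 1 of 19) lists also passed upward, with the same counts adjusted over the list alone except for 10 higher genes of ribosome biogenesis and MYC targets. Their camera adjusted p values were 2.94e-05, 3.99e-04, 3.99e-04 and 0.00122, and adjusted p = 0.634, 0.634, 0.360 and 0.286 with an estimated correlation. Within PLC/PRF/5, the respiratory chain (7 higher and 15 lower) and endoplasmic reticulum stress (3 and 6) lists did not pass (camera adjusted p = 0.760 and 0.595). Within MHCC97H, the mitochondrial ribosome (1 and 12) and ribosome biogenesis (0 and 2) lists did not pass (camera adjusted p = 0.0831 and 0.306). Fry passed the mitochondrial ribosome list downward in MHCC97H (fry adjusted p = 0.0118). It also passed the endoplasmic reticulum stress list downward in PLC/PRF/5 (fry adjusted p = 0.00446). In the difference, fry did not pass the respiratory chain and ribosome biogenesis lists (fry adjusted p = 0.127 and 0.0952). There it passed the mitochondrial ribosome and endoplasmic reticulum stress lists upward (fry adjusted p = 0.0200 and 0.00426). Serine and other amino acid synthesis (2 higher and 8 lower of 18, and 3 and 8 over the list alone), the ATF4 and integrated stress response (3 and 10 of 24 both ways) and hypoxia-inducible genes (1 and 4 of 16, and 1 and 6 over the list alone) passed downward. Their camera adjusted p values were 0.0109, 0.0113 and 0.0310, and adjusted p = 0.438, 0.438 and 0.597 with an estimated correlation. The serine call was lost without MHCC97H control replicate 1 (camera adjusted p = 0.0538), the stress response call without PLC/PRF/5 tigecycline replicate 2 (0.0541), and the hypoxia call without MHCC97H control replicate 1 (0.0538), MHCC97H tigecycline replicate 1 (0.117) or PLC/PRF/5 control replicate 2 (0.0518). Limma called 2275 genes, 1027 higher and 1248 lower, or 1148 higher and 1076 lower under median-of-ratios scaling and 1220 higher and 1036 lower under upper-quartile scaling. The count without 1 library was 1515, 1305, 905 and 1222 for MHCC97H control replicates 1 and 2 and tigecycline replicates 1 and 2, and 643, 674, 734 and 1180 for those of PLC/PRF/5. The few measured markers of other cell types did not pass (camera adjusted p = 0.903, 0.597, 0.787 and 0.928 for leukocytes, fibroblasts, endothelial cells and cholangiocytes). Fry passed the endothelial list of 3 measured genes downward (fry adjusted p = 0.0488).

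Of the remaining lists, 8 passed camera in no comparison. In MHCC97H, PLC/PRF/5 and the difference between them, the adjusted p values were 0.353, 0.955 and 0.582 for mitochondrial gene expression factors, 0.293, 0.458 and 0.890 for mitochondrial chaperones and proteases, and 0.389, 0.458 and 0.903 for the tricarboxylic acid cycle. They were 0.129, 0.580 and 0.892 for p53 targets, 0.162, 0.458 and 0.903 for Wnt targets, and 0.845, 0.200 and 0.374 for metallothioneins. They were 0.994, 0.604 and 0.999 for matrix and mesenchymal genes and 0.263, 0.888 and 0.458 for replication-dependent histones.

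Of the genes called in both lines, 368 rose in both and 612 fell in both, against 94.1 and 297.9 for independent lists of the same sizes. In opposite directions, 90 and 92 moved, against 192.2 and 145.9. Both tests used the same variance per gene, so calls can coincide more often than in independent lists, and no test allowed for this. The 980 genes changed the same way in both lines were 449 to 772 without 1 library, and 615, 519, 563, 496, 449 and 522 without MHCC97H control replicate 1, tigecycline replicates 1 and 2, PLC/PRF/5 control replicates 1 and 2 and tigecycline replicate 1. NIBAN1, AREG, SESN2, DDIT3, TRIB3 and LONP1 were among those that rose in both, and CDK1, CCNB1, DHCR7 and FGB among those that fell in both. The log2 fold changes of the lines correlated at Pearson r = 0.204 and Spearman rho = 0.232 across 17141 genes, which are not independent replicates. A model with the line as a covariate called 2295 genes with tigecycline, 751 higher and 1544 lower, or 1254 higher and 859 lower under median-of-ratios scaling and 978 higher and 1036 lower under upper-quartile scaling. This count fell to 1163, 1088, 1270 and 1261 without PLC/PRF/5 control replicate 1, control replicate 2, tigecycline replicate 1 and tigecycline replicate 2.

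The control cells of the lines differed far more than tigecycline changed either. UCA1, a noncoding RNA, was at 1712 ± 77.8 TPM in PLC/PRF/5 and higher than in MHCC97H by 10.53 on the log2 scale, and the plasma protein genes SERPINA1, PZP and A2M were also higher in PLC/PRF/5, with log2 differences of 10.39, 10.05 and 9.88. The aldo-keto reductase gene AKR1B10 was at 4030 ± 86.6 TPM in MHCC97H and 0.335 TPM in PLC/PRF/5 (log2 difference -11.56), and the calcium-binding S100A6, S100A11 and S100A4 followed with -10.91, -10.74 and -10.24. Limma called 12087 genes between the controls, 7095 higher and 4992 lower in PLC/PRF/5, or 5820 higher and 6010 lower under median-of-ratios scaling and 6185 higher and 5658 lower under upper-quartile scaling. The median log2 difference of all genes was 0.21, and another scaling moved it by -0.21 (median-of-ratios) or -0.15 (upper-quartile).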

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

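The limit to splits balanced over the lines, the tests of scaling, of interferon genes below 10 TPM and of poly(A)-lacking RNAs, and the pathways of the table's annotation, were chosen only after the results they bear on were seen. The other tests in this part were written for patterns already seen, though before their own results. The test of low starting levels in interferon genes was divided at 10 TPM after its result was seen. The 8 libraries have 18 splits with 2 libraries of each line on each side, and the real split was the 1 with as many as 2295 genes changed across both lines, where the highest other split gave 1. These splits are too few for a share under 0.05. Each was fitted with only the line beside it, so other splits left all or part of the tigecycline change in the residual spread. Low counts were therefore built in. The split of MHCC97H controls and PLC/PRF/5 tigecycline libraries against the rest gave 1 gene. The fit with a mean per group called 2275 genes for that difference between the lines. The split counts therefore cannot tell whether chance gave the 2295 genes.

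The change with tigecycline differed between the lines for 2275 genes, and for 82 of the 130 genes named and tested, a share raised by the naming rule, which took some genes for their difference (13.3% of all tested genes differed). All differences given here are log2 values, PLC/PRF/5 minus MHCC97H, past limma's test of the difference or camera's. Lists with a higher median difference were DNA replication (0.54), cytosolic ribosomal proteins (0.32), endoplasmic reticulum stress (0.28), ribosome biogenesis and MYC targets (0.26), the respiratory chain (0.21) and the mitochondrial ribosome (0.10), none of which passed with an estimated correlation (adjusted p = 0.286 to 0.634). Lists with a lower median were interferon-stimulated genes (-0.95), the ATF4 and integrated stress response (-0.30), amino acid synthesis (-0.30) and hypoxia-inducible genes (-0.30), none of which passed with an estimated correlation either (adjusted p = 0.286 to 0.597). Of the pathways named in the table's annotation, DNA replication (0.38), ribosome biogenesis in eukaryotes (0.21) and the proteasome (0.15) differed, and none passed with an estimated correlation (adjusted p = 0.780).

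Stress response and amino acid genes with a difference were ASNS (-1.58), ATF4 (-0.70), CBS (-1.37), CHAC1 (-1.91), DDIT4 (-1.37), GARS1 (-0.55), GDF15 (-2.21), PHGDH (-2.27) and PSAT1 (-0.82). SARS1 (-0.44), SESN2 (-1.16), SLC7A5 (0.64), TRIB3 (0.59) and WARS1 (0.49) belonged to the same themes. Interferon genes with a difference were DDX58 (-1.34), IFIT1 (-4.10), ISG15 (-3.03), ISG20 (-1.27), OAS1 (-1.61), OASL (-2.49) and STAT2 (-0.76). Proliferation genes with a difference were CCNE2 (1.42), MCM2 (0.59), PCNA (0.59), RRM2 (0.86), TYMS (1.18) and UHRF1 (1.28). Ribosomal genes with a difference were RPL12 (0.62), RPS19 (0.75), RPS21 (0.78), RPS26 (0.54), RPS6 (0.28), RPS9 (0.69), RPSA (0.62), RRP9 (0.68) and MRPL21 (0.93). Mitochondrial genes with a difference were MT-ATP6 (-0.45), MT-CYB (-0.70), MT-ND1 (0.41), MT-ND4 (-0.45), NDUFB9 (0.77) and NDUFS4 (0.80).

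Metabolic and chaperone genes with a difference were CALR (0.66), PDIA4 (0.64), HSPB1 (0.42), PDK4 (-2.20), PFKFB3 (-0.71), MAP1LC3B (-1.07), CKB (-2.62) and FABP1 (-3.43). AKR1C1 (0.89), AKR1C2 (1.25) and FTH1 (0.81) of the NRF2 targets differed too. Hypoxia-inducible genes with a difference were EGLN1 (1.09), NDRG1 (-3.58) and VEGFA (-0.77). Secreted and signalling genes with a difference were AREG (-2.14), BIRC3 (1.77), CGA (-3.19), CXCL1 (1.34), CXCL8 (4.21), IGFBP1 (-4.31), INHBE (1.74), ITPKA (-3.43), SEMA3D (-2.93) and THBS1 (3.48). Others were ASB4 (2.61), BEX2 (2.28), BOLA2 (5.22), CLDN2 (3.41), ITM2A (3.60), S100P (2.89), TRIM29 (3.23) and UBD (3.66). Noncoding RNAs with a difference were H19 (-2.30), VPS13B-DT (-2.77), the RNA5-8SN1, RNA5-8SN2, RNA5-8SN4 and RNA5-8SN5 copies (7.67 each), SNORA22 (-6.15) and SNORA63 (5.84), the last 2 on values listed at 0 in some groups.

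Without at least 1 of the 8 libraries, 26 of these 82 gene differences were lost. They were those of BOLA2, CCNE2, CKB, DDX58, FTH1, H19, HSPB1, INHBE, ISG20, ITM2A, MCM2, MT-ATP6, MT-ND1, MT-ND4, OAS1, PCNA, PFKFB3, RPS6, RRP9, SARS1, SLC7A5, STAT2, THBS1, TRIB3, UHRF1 and WARS1.

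Interferon-stimulated genes fell in PLC/PRF/5, and their difference from MHCC97H passed camera at the preset correlation. With an estimated correlation neither call was kept (adjusted p = 0.128 in PLC/PRF/5 and 0.286 in the difference). A starting level in MHCC97H too low to leave room to fall is argued against for the 6 members at 10 TPM or more in its controls (ISG15, ISG20, OAS1, OAS3, STAT2 and IRF1). They had a median difference of -1.11, and -1.33 to -0.89 without 1 library. Of these, ISG20 and IRF1 did not fall in PLC/PRF/5 (0.21 and 0.06), ISG20 rose by 1.47 in MHCC97H, and the differences of OAS3 (-0.95, limma adjusted p = 0.0539) and IRF1 (0.16) were not called. OAS1 and OAS3 had lower values with tigecycline in MHCC97H too (-0.72 and -0.96), against -2.32 and -1.91 in PLC/PRF/5. ISG15 started at 61.1 TPM in MHCC97H, far below its level in the PLC/PRF/5 controls. Whether a lower start than in PLC/PRF/5 matters, beyond room to fall, was not tested. For the other 15 members a low start stays open, since their median control level in MHCC97H lay only 0.72 on the log2(TPM + 1) scale (0.62 to 0.81 without 1 library) above the size of their median fall in PLC/PRF/5. A single PLC/PRF/5 library is also argued against, because the median fall was at least as large as -1.24 in every fit without 1 library. A difference in interferon signalling between the lines may underlie it and stays open as a hypothesis, since no test here measured signalling.

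Cytosolic ribosomal protein genes rose in PLC/PRF/5 relative to MHCC97H, with a median difference of 0.32 and 34 of 78 members called higher. The list did not pass with an estimated correlation (adjusted p = 0.438). Scaling of the libraries to a fixed total is argued against as the whole cause, since the median difference was still 0.260 under the scaling of 4 that lowered it most, and at least 0.222 when 1 library was also left out. A bias toward short transcripts stays open and may account for much of the difference, because other protein-coding genes matched on length and level had a median difference of 0.234 (0.163 to 0.266 over 1000 draws). The matching was imperfect, with a median length of 842.3 bases and a mean log2 TPM of 9.90 in the matched genes against 787.5 bases and 10.6 in the list. A biological difference between the lines was not tested apart from it.

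Mitochondrial RNAs moved apart, with rises in MT-ND1, MT-ND2 and MT-CYB and falls in MT-RNR2 and MT-ND6. Lower recovery of RNAs without poly(A) tails may explain the rRNA values in MHCC97H, where 5 such nuclear RNAs (RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1) had a median of -1.21 (-1.21 to -0.92), and this stays open. Of these, RPPH1 had 0.27 (limma adjusted p = 0.775) and RN7SL1 was not called (-0.92, limma adjusted p = 0.0518). Lower recovery is argued against in PLC/PRF/5, where the median of the same 5 RNAs was 1.19 (0.76 to 1.63). All 5 had positive values there, but RN7SL1, RN7SL2 and RMRP were not called (limma adjusted p = 0.0659, 0.220 and 0.0790). TERC, also chosen for this test, was not among the tested rows. The row used for RMRP, a symbol on more than 1 row, was corrected after a first result was seen, and both directions were as before.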

How the results depend on the processing

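Leaving out rows shorter than 300 bases, and the concern with PLC/PRF/5 tigecycline replicate 2, were chosen after seeing the data. Across all settings, 3880 of the alternative values for 244 named gene results kept their direction and side of the threshold, 351 kept direction but were no longer past it, 10 came to pass it and 4 reversed. For 42 list results, 709 kept both, 78 were no longer past the threshold and 0 reversed. The reversed values were small and not called: CDKN1A in MHCC97H ranged from -0.0351 without control replicate 2 to 0.52 without control replicate 1. HSPA5 in PLC/PRF/5 was 0.13 under median-of-ratios scaling and 0.10 under upper-quartile scaling, and ranged from -0.0208 without control replicate 2 to 0.0017 without control replicate 1. The cause was not tested.

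With an absolute log2 fold change of at least 1, 591 genes were called in MHCC97H, 981 in PLC/PRF/5, 945 in the difference between the lines, 282 across both lines, 91 the same way in both and 6746 between the control lines. At an adjusted p under 0.01 the counts were 970, 1873, 414, 661 and 312 for the first 5. Fewer genes pass by the construction of these thresholds. Without a filter, 1398 genes differed between the lines, 1335 changed across both and 646 changed the same way in both; the cause was not tested. With each line fitted alone, MHCC97H gave 108 genes, PLC/PRF/5 gave 3149 and 52 changed the same way in both. The main fit shared 1 variance per gene between the lines, so its MHCC97H calls rested in part on the spread of PLC/PRF/5 libraries. The median absolute log2 difference between replicates was 0.163 and 0.144 in MHCC97H controls and tigecycline, and 0.113 and 0.135 in those of PLC/PRF/5. How much this or the fewer libraries lowered the counts was not tested. Without 1 library, counts ranged from 1239 to 2271 in MHCC97H, 1929 to 4582 in PLC/PRF/5, 643 to 1515 in the difference, 1088 to 2118 across both lines, 449 to 772 the same way in both and 10737 to 11983 between the control lines. A group left with 1 library was assumed to vary like the others. With an estimated correlation camera passed 0 lists in MHCC97H, 0 in PLC/PRF/5 and 0 in the difference, while fry passed 23, 22 and 15. Without 1 library, camera passed 14 to 17, 13 to 16 and 8 to 11. Without rows shorter than 300 bases the counts were 2773, 4698 and 2358 for the lines and their difference.

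Replicate numbers did not pair the samples, since deviations of libraries with the same number correlated at 0.0315 in MHCC97H and 0.0225 in PLC/PRF/5. With the number as a replicate block the counts were 1951 in MHCC97H, 3834 in PLC/PRF/5, 1113 in the difference, 869 across both lines and 742 the same way in both. The cause was not tested.

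Of named gene calls, 9 of 61 in MHCC97H, 14 of 76 in PLC/PRF/5 26 of 82 in the difference and 0 of 8 between the control lines were lost without at least 1 library. With each line fitted alone, 38 of 61 in MHCC97H and 14 of 76 in PLC/PRF/5 were lost. With the replicate block, 5, 4 and 11 were lost in MHCC97H, PLC/PRF/5 and the difference. The planned count-model and limma-voom alternatives were not run, because the values were TPM. What read depth limits was not tested, since TPM keep no read totals.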

Other observations

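The pathways and the random lists in this part were chosen only after the data were seen. Of 298 pathways named in the table's annotation, camera passed 9 in MHCC97H, and 0 with an estimated correlation (adjusted p = 0.804 for those 9). Proteasome genes were among them, with 18 of 49 lower with tigecycline and none higher (median log2 fold change -0.26, camera adjusted p = 3.18e-04). Spliceosome genes had 35 of 156 lower and 2 higher (median -0.22, adjusted p = 0.00814), and fatty acid degradation genes 11 of 37 lower and 2 higher (adjusted p = 0.0225). Genes of terpenoid backbone synthesis, which feeds cholesterol synthesis, had 9 of 22 lower and none higher (adjusted p = 0.0319), and drug metabolism by other enzymes 17 of 65 lower and 4 higher (adjusted p = 0.0413). Mitophagy genes passed upward, with 11 of 79 higher and 4 lower (adjusted p = 0.0319). DNA replication (23 of 40 lower and 2 higher), cell cycle (44 of 132 lower and 4 higher) and steroid biosynthesis (9 of 22 lower and none higher) passed with adjusted p = 2.06e-07, 0.00747 and 3.18e-04.

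In PLC/PRF/5 3 pathways passed, and 0 with an estimated correlation (adjusted p = 0.889 for those 3). Steroid biosynthesis genes had 15 of 22 lower and none higher (adjusted p = 0.00559), ribosome biogenesis in eukaryotes 20 of 97 higher and 12 lower, and aminoacyl-tRNA biosynthesis 17 of 47 higher and 8 lower (adjusted p = 0.0244 each). In the difference between the lines, where 0 passed with an estimated correlation (adjusted p = 0.780), DNA replication (13 of 40 higher and 1 lower), ribosome biogenesis (18 of 97 higher and 2 lower) and the proteasome (8 of 49 higher and none lower) passed with adjusted p = 9.34e-04, 0.00365 and 0.00486.

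The 24 measured genes of the ATF4 and integrated stress response list differed less between the lines after tigecycline than before it. The SD of their log2 differences between the lines was 1.77 in controls and 1.28 with tigecycline, a ratio of 0.721, and 0.664 to 0.757 without 1 gene. Of 10000 random lists matched on mean expression, 1.67% had a ratio as small, and their central range was 0.753 to 1.26. These lists were not matched on response to tigecycline or on the difference between the control lines. The share therefore cannot tell whether the narrowing was particular to this list or shared by other strongly changed genes. Without GDF15 the ratio was 0.757, inside that range. No explanation for the narrowing was tested.

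The sum of the mitochondrial rRNAs was 7161 and 4611 TPM in the MHCC97H controls and 2941 and 2961 TPM with tigecycline, and 9958 and 9224 TPM in the PLC/PRF/5 controls and 4694 and 6789 TPM with tigecycline.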
